A study of Mus musculus with 12 samples.

How the data were processed

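ATAC-seq libraries of 12 samples of mouse RAW264.7 macrophage lines were used, in 4 groups of 3 taken from the titles and characteristics: GFP line untreated, GFP line with LPS, Nur77 line untreated and Nur77 line with LPS. Per the labels, tagmentation ran for 45 min at 37 °C and fragments under 700 bp were kept. Each library was given as 1 narrowPeak list, called separately. Per the submitters' processing notes, cutadapt 2.6 and DiffBind 3.0.15 were used and the build was mm10. The aligner and the peak caller are not given in the sources used here. Peak names in the deposited lists record a mapping quality of 20, removal of mitochondrial and duplicate reads, and a q value of 0.001.

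The score in the deposited lists is the authors' whole number per peak, equal to the whole part of 10 times the -log10 q in 99.18% to 100.0% of the peaks of a list. The deposited fold values are the authors' enrichment of the summit over the caller's background, as a ratio. The -log10 p and -log10 q columns are the authors' values at the summit, and the lowest -log10 q ran from 3.038 to 3.757 over the lists. Scores, folds and q values are the authors' own and served only to describe, rank or filter peaks within a list.

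Rows sharing start and end were collapsed to 1 peak, and peaks on chromosomes 1 to 19, X and Y were kept. Peaks overlapping or touching across the 12 lists were merged with bedtools 2.31.1 into 100374 regions, of which the 76042 present in at least 2 lists were used. A library called a region when a peak of it overlapped by at least 1 bp. Coordinates are printed with 1-based starts, each 1 above the 0-based start in the lists. Regions were assigned to genes by their distance to the span of protein-coding genes in a RefSeq table of the same build (21887 genes). This table gives no strand, so promoters and transcription start sites were replaced by either end of the gene, within 1000 bp, and 50 kb distances were measured from the gene span. Motif scans, planned for 12 motifs including AP-1, NF-kB and the Nur77 element, were not run because no genome sequence was at hand. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

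Read totals are not part of the lists. The deposited fold values of each list lie on an even grid, from which a background height per library was derived as the value that makes fold times background plus 1 a whole number of reads. With a tolerance of 0.1 reads, 100.0% of the folds met it in every list. Background heights of replicates 1, 2 and 3 were 0.919, 0.964 and 1.14 in GFP untreated, 0.411, 0.676 and 1.45 in GFP LPS, 0.759, 0.402 and 1.254 in Nur77 untreated, and 0.988, 0.665 and 0.612 in Nur77 LPS. On simulated lists with known background the derivation returned the true value. The background height served as a stand-in for depth, since lists with a higher one reach weaker regions.

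For each comparison of 3 libraries with 3, gained and lost regions were counted as defined in the report. Across 6 against 6 libraries, a two-sided Fisher's exact test was run on regions called in 4 to 8 of the 12, with Benjamini-Hochberg adjustment at 0.05. Differing responses were set against relabellings of the line within each treatment, 100 drawn from 200. Peak number, covered length and gene-end share were tested by exact permutation within strata, 6 tests adjusted together. Similarity of lists was tested with 100000 permutations. For each of 15 gene lists (182 genes, 180 matched as protein-coding) and each comparison and direction, separating regions near the list were set against regions called in exactly 3 of the same 6 libraries without separating the groups, by two-sided Fisher's exact test adjusted over 120 tests. The lists were macrophage identity, cytokines and chemokines, NF-kB feedback and signalling, AP-1 family, other immediate early genes, interferon response, anti-inflammatory and resolution genes, nuclear receptors, lipid and energy metabolism, housekeeping, and markers of T cells, B cells, fibroblasts, epithelium and neurons. In the interferon list 14 of 16 genes were used, and 5 of 7 fibroblast markers had regions nearby.

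The regions named are those at the Nr4a1 locus, the 10 gained and 10 lost regions per comparison with the highest mean percentile, and up to 30 regions per comparison within 50 kb of a list gene. Some regions that this rule picks are not reported here. A percentile is the rank of a peak by -log10 q within its own list in the deposited data, averaged over the libraries that called it. Replicate numbers follow the titles and were not used to pair samples. Most tests, the regions, gene lists, naming rule and most alternatives were fixed before the data were examined. The background height, its thresholds at 10 and 20 times, the random gene lists and the work on chromosome 12 were chosen afterwards.

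Alternatives were lists trimmed to the length of the shortest (36184 peaks), the strongest 20000 peaks, a -log10 q of at least 5 in the deposited lists, other support and overlap rules, windows round summits, other gene distances, tests within strata, a block by replicate number, and each library left out in turn. Simulated calls with no group difference used each region's call rate scaled by the library's relative rate, capped and assumed independent between libraries. The call rates of libraries and regions were therefore kept only approximately. The region rates include any real group differences. On simulated data with 2000 changed regions the test of 6 against 6 called most of them, and with 200 it called 0. In the lists as deposited, 470 regions separated all 12 libraries by LPS and 476 by line, and still 0 passed adjustment. A result of 0 regions past adjustment therefore leaves open changes in at least this many regions. Calls are present or absent, so changes in height at regions open in both groups were not measured, apart from the ranks compared on chromosomes.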

Results

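Open chromatin was profiled by ATAC-seq, an assay in which a transposase tags accessible DNA, in RAW264.7 cells, a mouse macrophage line. The stable lines carried a doxycycline-inducible gene for Nur77, a nuclear receptor encoded by Nr4a1, or for green fluorescent protein (GFP). Expression was induced with 1 µg/ml doxycycline for 18 h, and the cells were left untreated or given 500 ng/ml lipopolysaccharide (LPS), a bacterial endotoxin, for 1 h. The 4 groups held 3 libraries each, and each library was represented by 1 list of peaks in mm10 coordinates. Nothing in the labels states that replicates were separate cultures, so p-values of tests across libraries measure the spread between these samples, which may be technical. Regions are the units in the tests of gene-list enrichment, gene ends and overlap. Their p-values do not measure the spread between libraries.

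The untreated GFP libraries held 54515, 65014 and 65061 peaks for replicates 1, 2 and 3, and the LPS-treated GFP libraries held 48275, 56888 and 81467. The untreated Nur77 libraries held 55656, 36184 and 55446 peaks, and the LPS-treated Nur77 libraries held 59858, 44790 and 52895. The group means were 61530 ± 6075 and 62210 ± 17224 peaks in untreated and LPS-treated GFP cells, and 49095 ± 11182 and 52514 ± 7541 in Nur77 cells (SD, n = 3 each). Read totals were not used here. The background height that each list implies, which stands for depth, ran from 0.402 to 1.45 reads, a 3.61-fold range. A peak had to reach at least 5 to 8 reads to be listed, depending on the library, so a weak region missing from a list was not detectable at that depth rather than shown to be closed.

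**Figure D1:**
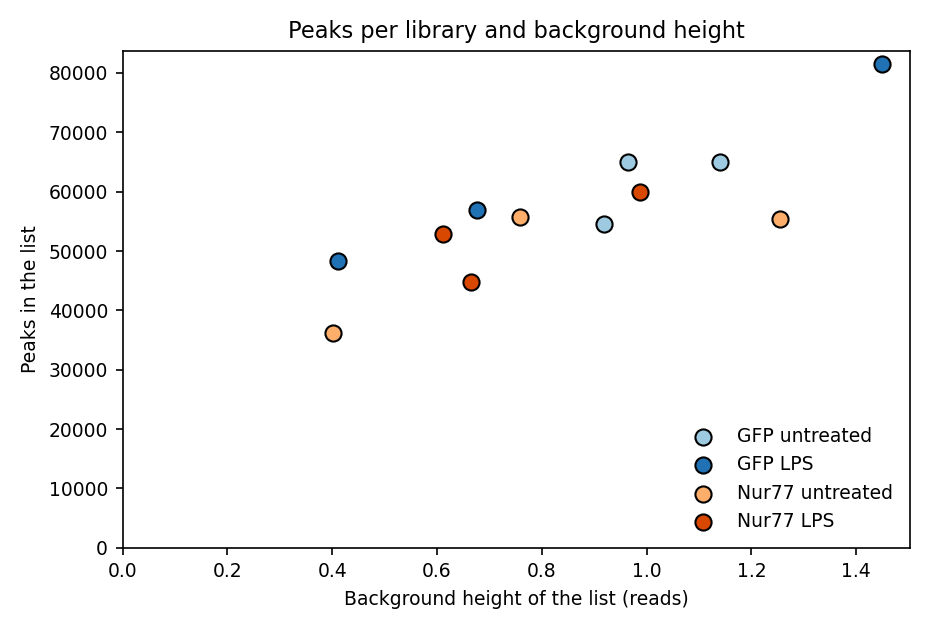
Number of peaks in each of the 12 lists (vertical axis) against the background height the list implies, in reads (horizontal axis), with 1 point per library coloured by group. The longest list, with 81467 peaks, has the highest background height (1.45), and the shortest, with 36184 peaks, has the lowest (0.402).

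The peaks of all lists were merged into 76042 regions present in at least 2 lists, and 26378 of these (34.7%) were called in all 12 libraries. Lists of one group shared more of their covered bases (mean Jaccard index 0.634) than lists of different groups (0.594, permutation test, one-sided p = 0.00055). This did not hold in each group: LPS-treated GFP lists shared 0.564 with one another and 0.597 with LPS-treated Nur77 lists, and untreated Nur77 lists shared 0.611 with one another and 0.616 with untreated GFP lists. For a comparison of 3 libraries with 3, a region was termed gained when it was called in 3 of 3 libraries of the first group and 0 of 3 of the second, and lost in the opposite case. With equal call rates in the 6 libraries, chance gives each pattern in 5% of the regions called in exactly 3 of them. Call rates differed, so counts of unchanged regions in simulated calls scaled to each library's rate are given beside each comparison. In the lists as deposited, splits by background height that mix the groups gave more separating regions than these simulations. The simulated counts therefore understate what differences in depth can give. A single region cannot reach a two-sided exact p below 0.1 in such a design. Within-list ranks are given as percentiles of the authors' -log10 q, with 100 as the strongest peak, and describe how prominent a region was where it was called.

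The Nr4a1 locus served as a check of the line labels. A region inside the gene, on chromosome 15 from 101270092 to 101272260, was called in 6 of 6 Nur77 libraries and 0 of 6 GFP libraries, at a mean percentile of 35.3 ± 10.1 (SD, n = 6). The authors' fold enrichments of its peaks in the Nur77 libraries lay between 7.13 and 12.61. Of the other regions within 10 kb of the gene, the most prominent lay 4.8 kb from it, at 101245616 to 101249122, and was called in all 12 libraries, at percentile 97.4 ± 1.2 (SD, n = 12). The lists do not separate reads of the native gene from reads of the introduced Nur77 sequence.

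**Figure D2:**
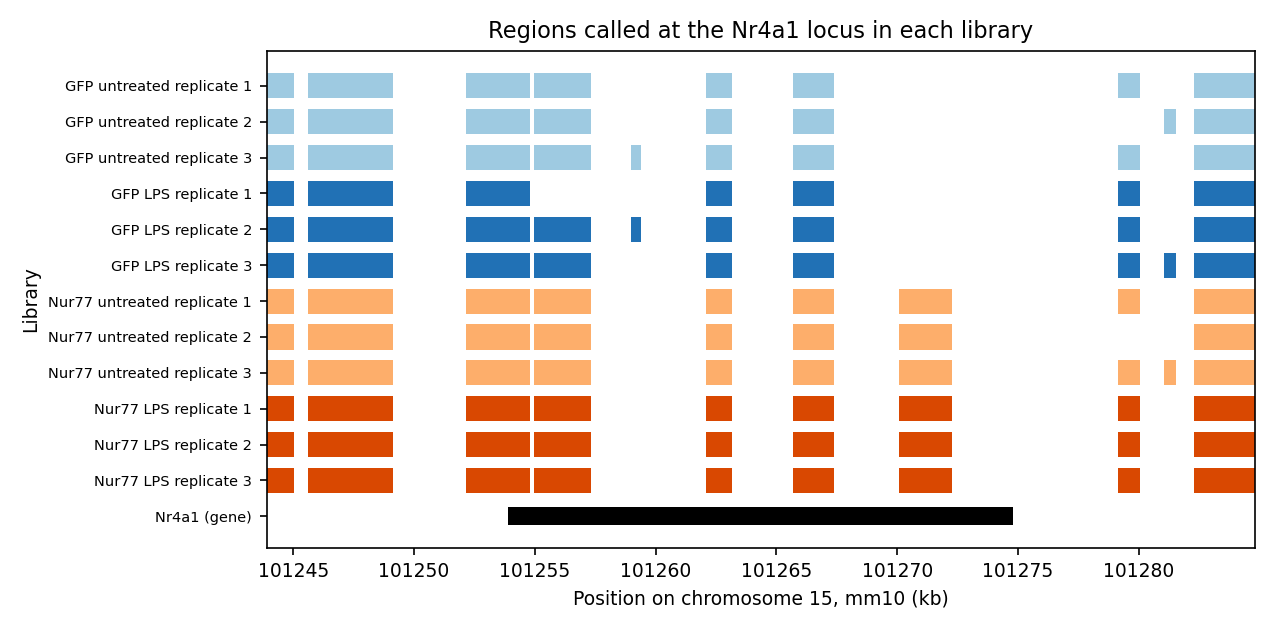
Regions called in each of the 12 libraries (one line of boxes per library, coloured by group) along chromosome 15 at Nr4a1, with position in kb in mm10 coordinates on the horizontal axis and the gene as a black bar. The region at 101270092 appears in the 6 Nur77 libraries and in none of the GFP libraries.

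The first question was how 1 h of LPS altered accessibility in these macrophages. In both lines, 432 regions were called in all 6 LPS libraries and in none of the 6 untreated libraries. The most prominent lay at Acod1, which encodes the enzyme that makes itaconate in activated macrophages (chromosome 14, 103046297 to 103047818, percentile 88.1 ± 2.5, n = 6). The next was 34.3 kb from Nfkbiz, which encodes a nuclear inhibitor of the NF-kB family (chromosome 16, 55776063 to 55777038, 85.6 ± 2.4, n = 6). Others lay inside Nfkb1, the gene of an NF-kB subunit (chromosome 3, 135639377 to 135641929, 77.0 ± 4.6, n = 6), Lyn, a Src-family kinase gene (76.7 ± 8.1, n = 6), Anxa5 and Arhgef3. Another was 3.0 kb from Mmp14, a membrane-bound matrix protease gene (76.9 ± 6.8, n = 6). In the opposite direction, 38 regions were called in all untreated and no LPS libraries, at Magi1 (56.8 ± 5.4, n = 6), at Ccnd1, the gene of cyclin D1 (53.8 ± 5.1, n = 6), at Gas6, whose product is a ligand of receptors for apoptotic cells (40.8 ± 8.3, n = 6), and at Lats2, a kinase gene of the Hippo pathway (33.2 ± 9.2, n = 6).

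Among the gene lists fixed in advance, some regions within 50 kb of the list genes were more often called after LPS when adjusted over the list alone, and 0 of them when adjusted over all regions. For NF-kB feedback and signalling, 11 of 75 tested regions were more often and 1 less often called across the 12 libraries. They lay near Nfkb1, Nfkbib, Nfkbiz, Rel, Traf1, Tnip1 and Tnfaip3, the last of which encodes the NF-kB brake A20. The region less often called was 8.7 kb from Ier3. For cytokines and chemokines, 5 of 46 regions were more often called, near Il1a, Il1b, Csf2, Ccl5 and Nos2, which encode interleukins, a growth factor, a chemokine and the inducible nitric oxide synthase, and 1 region 42.9 kb from Tnf was less often called. For the AP-1 family, 3 of 55 regions were more often called, near Batf and Maff, and this list passed no enrichment test in either line. Lists of markers of other cell types also held such regions, 1 of 8 regions near T cell markers (Cd4), 1 of 18 near fibroblast markers (Pdgfrb) and 1 of 14 near epithelial markers (Epcam). The other lists had no region past the threshold in this comparison. These counts come from two-sided Fisher's exact tests on 6 against 6 libraries with Benjamini-Hochberg adjustment.

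Adjusted over all 20292 regions tested, the count of LPS regions past 0.05 was 0 in Fisher's exact test, at a lowest adjusted p of 0.0935. At an unadjusted p under 0.05, 1129 regions were more often and 300 less often called after LPS. The smallest p that 6 against 6 can give is 0.00216, and in lists of equal length 547 regions were more often and 95 less often called after adjustment. There 10423 regions were tested, and the numbers that passed equal those called in all against none (547) and in none against all (95).

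In the GFP line alone, LPS was accompanied by 1487 gained and 777 lost regions, 17.5% and 9.1% of the 8496 regions called in 3 of the 6 libraries. Gained regions outside the shared set included one inside Thbs4, a thrombospondin gene (85.8 ± 5.8, n = 3), one inside Akap13, an anchoring protein gene (84.0 ± 5.6, n = 3), and one near Ccl5 (65.3 ± 11.9, n = 3). Regions 23.0 and 33.2 kb from Ccl2, a monocyte chemoattractant gene, were gained at lower ranks (50.8 ± 15.3 and 37.2 ± 18.6, n = 3 each). The most prominent lost regions included one 7.5 kb from Cited2 (60.7 ± 6.9, n = 3) and one 5.8 kb from Ifngr2, an interferon gamma receptor gene (60.2 ± 8.5, n = 3). Regions near the NF-kB list made up 1.48% of the gained regions against 0.32% of the comparison regions, which were called in 3 of the 6 libraries without separating the groups (22 against 20 regions, odds ratio 4.66, two-sided Fisher's exact test, p = 1.5e-06, adjusted p = 9.1e-05 over 120 tests). This call was lost with random gene lists that keep neighbouring regions together (permutation test, p = 0.0052, adjusted p = 0.12), in lists of equal length (odds ratio 4.66, exact test, p = 0.016, adjusted p = 0.74) and at 20 times background (odds ratio 3.48, exact test, p = 0.021, adjusted p = 0.5). The cytokine and chemokine list did not pass (10 against 12 regions, odds ratio 3.51, exact test, p = 0.0046, adjusted p = 0.092), but did within 100 kb (14 against 16, odds ratio 3.69, exact test, adjusted p = 0.036). In lists of equal length 477 of the gained and 38 of the lost regions were the same. In simulated calls 303 to 335 unchanged regions counted as gained and 328 to 345 as lost. With 1 library left out, gained regions numbered 3962 without LPS replicate 1 and 2350 without LPS replicate 2, and lost regions numbered 3650 without LPS replicate 3 and 1905, 1197 and 1217 without untreated replicates 1, 2 and 3.

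In the Nur77 line, LPS was accompanied by 1475 gained and 350 lost regions, 22.3% and 5.3% of the 6621 regions called in 3 of the 6 libraries. The most prominent gained region lay inside Ptprj, a receptor tyrosine phosphatase gene (93.3 ± 1.3, n = 3), and others lay at Acod1 (87.1 ± 1.8, n = 3), 34.3 kb from Nfkbiz (85.9 ± 3.1, n = 3) and inside Zeb2, a zinc finger repressor gene (81.6 ± 2.7, n = 3). A region 14.3 kb from Cxcl10, an interferon-inducible chemokine gene, was gained at 55.3 ± 11.4 (n = 3). The lost regions included Ccnd1 (56.2 ± 3.4, n = 3) and a region 4.0 kb from Arg1, the arginase gene (44.7 ± 10.7, n = 3). Regions near the NF-kB list (20 gained against 9 comparison regions, odds ratio 7.31, p = 2.6e-07, adjusted p = 3.1e-05) and near cytokine and chemokine genes (10 against 7, odds ratio 4.67, p = 0.0019, adjusted p = 0.045) were over-represented among the gained regions in two-sided Fisher's exact tests. Within 100 kb neither list passed in this line (exact test, adjusted p = 0.059 each), and no test compared the lines. Regions near lipid and energy metabolism genes were over-represented among the lost ones (6 against 14, odds ratio 5.96, exact test, p = 0.0016, adjusted p = 0.045), among them regions near Fasn, a gene of fatty acid synthesis, and near Idh2 and Sdhb, genes of mitochondrial energy metabolism. When whole genes were drawn at random to keep neighbouring regions together, no list passed in either line (permutation test, lowest adjusted p = 0.12). In lists of equal length only the cytokine and chemokine list in the Nur77 line passed, and lost regions numbered 663 against 350. Of the regions as deposited, 537 of the gained and 59 of the lost were the same in those lists.

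In simulated calls 427 to 478 unchanged regions counted as gained and 281 to 284 as lost in the Nur77 line. The count of 350 lost regions was little above that level. With 1 library left out, gained regions numbered 2807 without LPS replicate 2 and 2234 without untreated replicate 3. Lost regions numbered 2032 without untreated replicate 2 and 884 without LPS replicate 1.

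Gained regions in both lines lay less often within 1000 bp of the end of a protein-coding gene than comparison regions, at 5.4% against 7.8% in the GFP line (odds ratio 0.67, exact test, p = 0.0011, adjusted p = 0.0021) and 5.8% against 8.6% in the Nur77 line (odds ratio 0.66, exact test, p = 0.00051, adjusted p = 0.0014). Lost regions lay there more often, at 12.6% (odds ratio 1.71, exact test, p = 1.3e-05, adjusted p = 5.3e-05) and 18.6% (odds ratio 2.43, exact test, p = 1.6e-08, adjusted p = 1.3e-07). Of the regions that separated the lines, those gained in the Nur77 line after LPS lay there more often (13.4% against 7.9%, odds ratio 1.81, exact test, p = 0.0045, adjusted p = 0.0072). The regions lost after LPS (6.4%, adjusted p = 0.068) and those gained (10.3%, adjusted p = 0.56) or lost (8.3%, adjusted p = 0.31) in untreated cells did not pass the exact test. All were two-sided Fisher's exact tests on the lists as deposited, adjusted over 8 tests. Of the 777 and 350 regions lost with LPS, only 38 and 59 were the same in lists of equal length. Each region lost with LPS in the Nur77 line had to be called in untreated Nur77 replicate 2. That list had the highest share of peaks at gene ends (26.85%), and the p-values do not allow for this.

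**Figure D3:**
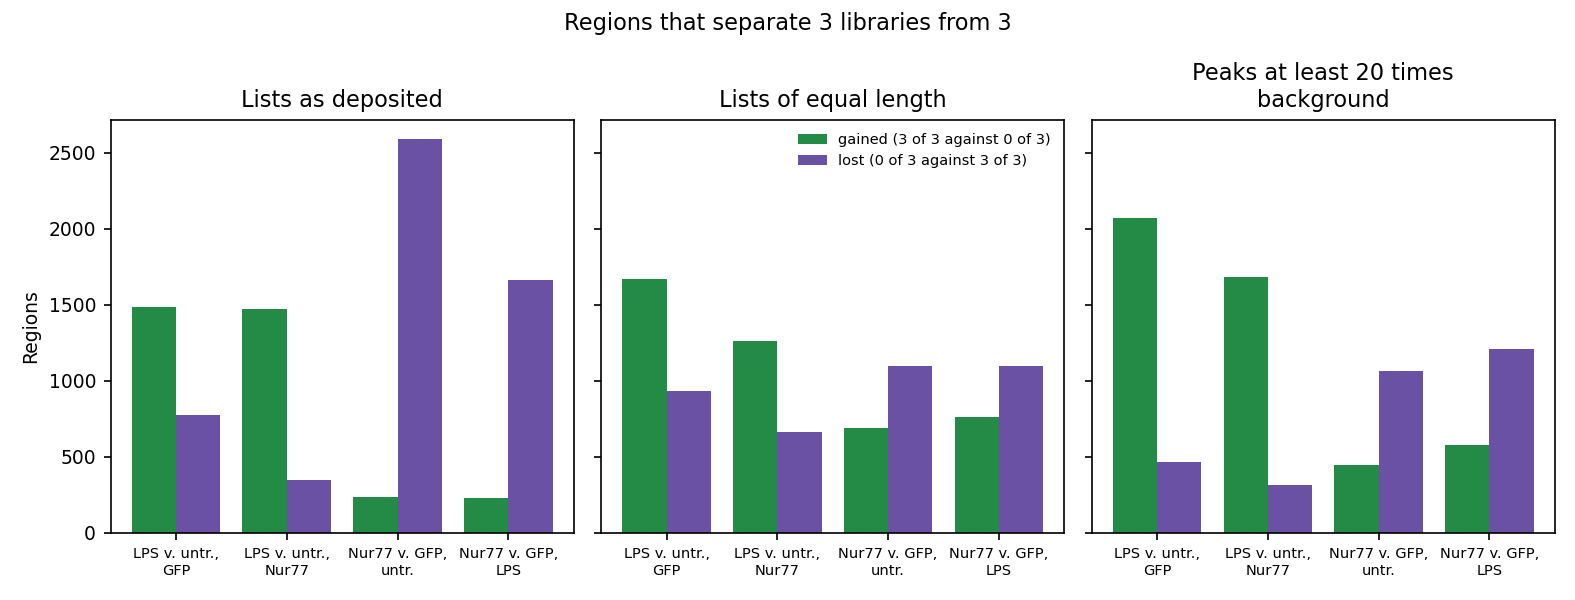
Number of regions gained (green) and lost (purple) in each of the 4 comparisons of 3 libraries with 3, for the lists as deposited, for lists of equal length and for peaks at least 20 times background (panels from left to right). LPS gave more gained than lost regions in each panel, and the Nur77 line had more lost than gained regions against GFP in each panel, with 2588 lost regions in untreated cells as deposited and 1095 in lists of equal length.

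The next question was how induced Nur77 altered accessibility before LPS. In untreated cells, 234 regions were gained and 2588 lost in the Nur77 line against the GFP line, 3.2% and 35.4% of the 7316 regions called in 3 of the 6 libraries. The most prominent gained regions lay inside Zic5, a zinc finger gene (80.7 ± 5.8, n = 3), Arhgef33 (79.0 ± 5.0, n = 3), Ece1, the endothelin-converting enzyme gene (78.6 ± 7.1, n = 3), and Rasgrf2, a gene of a Ras activator (76.2 ± 3.9, n = 3). The most prominent lost regions lay inside Klf6, a zinc finger factor gene (chromosome 13, 5860572 to 5862494, 87.7 ± 3.3, n = 3), Ppargc1a, which encodes the mitochondrial coactivator PGC-1alpha (84.4 ± 1.2, n = 3), and Pde7b (79.0 ± 1.7, n = 3). Lost regions near the macrophage identity list numbered 6, near Cd68, Cebpa, Cebpb, Itgam, Lyz2 and Runx1, and their share did not pass the test (odds ratio 0.58, two-sided exact p = 0.29, adjusted p = 1.0). Regions near lipid and energy metabolism genes were under-represented among the lost ones (1 against 22, odds ratio 0.08, exact test, p = 0.00069, adjusted p = 0.028, or 0.26 with random gene lists).

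In lists of equal length the same comparison gave 690 gained and 1095 lost regions, and 84 gained and 394 lost regions were shared with the lists as deposited. Among unchanged regions in simulated calls, 171 to 175 counted as gained and 649 to 710 as lost, against 234 and 2588 observed. Without 1 library, gained regions numbered 1193 without Nur77 untreated replicate 2, and lost regions numbered 5227 without GFP untreated replicate 1 and 4215 without Nur77 untreated replicate 3.

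After LPS, the Nur77 line had 231 gained and 1661 lost regions against the GFP line, 3.0% and 21.9% of the 7574 regions called in 3 of the 6 libraries. Arhgef33 (77.2 ± 3.1, n = 3), Zic5 (74.8 ± 6.5, n = 3), Ece1 (74.5 ± 3.6, n = 3) and Hmox2, the constitutive haem oxygenase gene (69.5 ± 3.0, n = 3), again held gained regions. Klf6 (89.7 ± 2.2, n = 3) and Ppargc1a held lost regions, and 3 more lay 73.8 to 92.0 kb from Plpp4, a phospholipid phosphatase gene. Near inflammatory genes, lost regions included one 25.6 kb from Il10, an anti-inflammatory cytokine gene (22.6 ± 7.0, n = 3), one 2.1 kb from Nfkb1 (30.5 ± 12.5, n = 3) and one 27.3 kb from Ptgs2, the cyclooxygenase-2 gene (15.8 ± 13.6, n = 3). A gained region lay 33.2 kb from Cxcl1 and 45.9 kb from Cxcl2, genes of neutrophil chemoattractants (11.2 ± 5.3, n = 3). All of these regions near inflammatory genes ranked low in their lists, where depth bears on whether a region is called. In the AP-1 family, lost regions lay near Batf3 and Fos, and the region near Fos is on chromosome 12. Of the 15 gene lists, 0 passed Fisher's exact test in either direction in this comparison, and 2 of the tests had an unadjusted p under 0.05 (interferon response among gained regions, exact p = 0.046, adjusted p = 0.51, and lipid and energy metabolism among lost regions, exact p = 0.02, adjusted p = 0.3). In simulated calls 217 to 218 unchanged regions counted as gained and 502 to 523 as lost. The count of 231 gained regions was hardly above that level. A split of the same 6 libraries by background height, which mixed the lines, gave 1712 separating regions against 1892 in the real split. The simulated level does not include this. Equal-length lists gave 763 gained and 1097 lost regions, of which 54 and 359 were the same as in the lists as deposited. Leaving out 1 library gave 718, 443 and 1382 gained regions without Nur77 LPS replicate 2, Nur77 LPS replicate 3 and GFP LPS replicate 3, and 5110, 2947 and 2876 lost regions without GFP LPS replicate 1, GFP LPS replicate 2 and Nur77 LPS replicate 1.

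Across both treatments, 44 regions were called in all 6 Nur77 and no GFP libraries, and 432 in all 6 GFP and no Nur77 libraries. The former included Arhgef33 (78.1 ± 3.9, n = 6), Zic5 (77.7 ± 6.4, n = 6), Ece1 (76.6 ± 5.5, n = 6) and the Nr4a1 region. The latter included Klf6 (88.7 ± 2.7, n = 6), Ppargc1a (82.2 ± 4.1, n = 6) and Setd4 (73.3 ± 4.9, n = 6). Regions at 82066790 to 82067514 and 82072098 to 82074118 on chromosome 11, within 50 kb of Ccl2 and Ccl7, genes of monocyte chemoattractants, were called in 6 of 6 GFP and 0 of 6 Nur77 libraries (50.7 ± 16.3 and 32.4 ± 19.5, n = 6 each). They were less often called adjusted over the list alone (2 of 46 regions, lowest adjusted p = 0.0498, two-sided Fisher's exact test), and the gene nearest to them was Ccl11. Of the 20292 regions tested over all, 0 passed after adjustment in Fisher's exact test (lowest adjusted p = 0.0923). In the strongest 20000 peaks of each list 66 were more often and 186 less often called. In lists of equal length (lowest adjusted p = 0.0592) and at 20 times background (0.0562), 0 passed the same exact test. Regions called in all 6 libraries of one side and 0 of the other share the smallest p, so they pass or fail together. Whether they pass depends on how many there are among the regions tested. The 0 here is therefore no contrast with the regions that passed for LPS. At an unadjusted p under 0.05, 132 regions were more often and 1486 less often called in the Nur77 line. The other gene lists had 0 regions past the threshold when adjusted over the list alone. In lists of equal length 112 regions were called in all Nur77 and no GFP libraries and 269 in the opposite case, and at 20 times background 103 and 281.

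Chromosome 12 held 4.7% of all regions but 12.4% of those lost in the Nur77 line in untreated cells, 12.5% of those lost after LPS and 15.3% (66 of 432) of those lost in both. Regions near Batf, Nfkbia, Fos, Rsad2 and Pxdn that were lost in the Nur77 line lie on this chromosome. Among the 26378 regions called in all 12 libraries, ranked within each library over these same regions, the 1054 regions of chromosome 12 had a median percentile of 42.9 ± 1.2 in the Nur77 libraries and 59.4 ± 1.1 in the GFP libraries (SD, n = 6 each). The difference was -16.5, with the 6 Nur77 values (42.1 to 45.1) below the 6 GFP values (58.1 to 61.3), and passed an exact permutation test within treatments (two-sided p = 0.005, the smallest it can give, adjusted p = 0.033 over 20 chromosomes). The next largest difference was 3.7, on chromosome X, higher in the Nur77 libraries (exact permutation test, p = 0.005, adjusted p = 0.033), and chromosome 5 passed at the same p with a difference of 1.1. This comparison was chosen after the lost regions had been counted per chromosome.

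**Figure D4:**
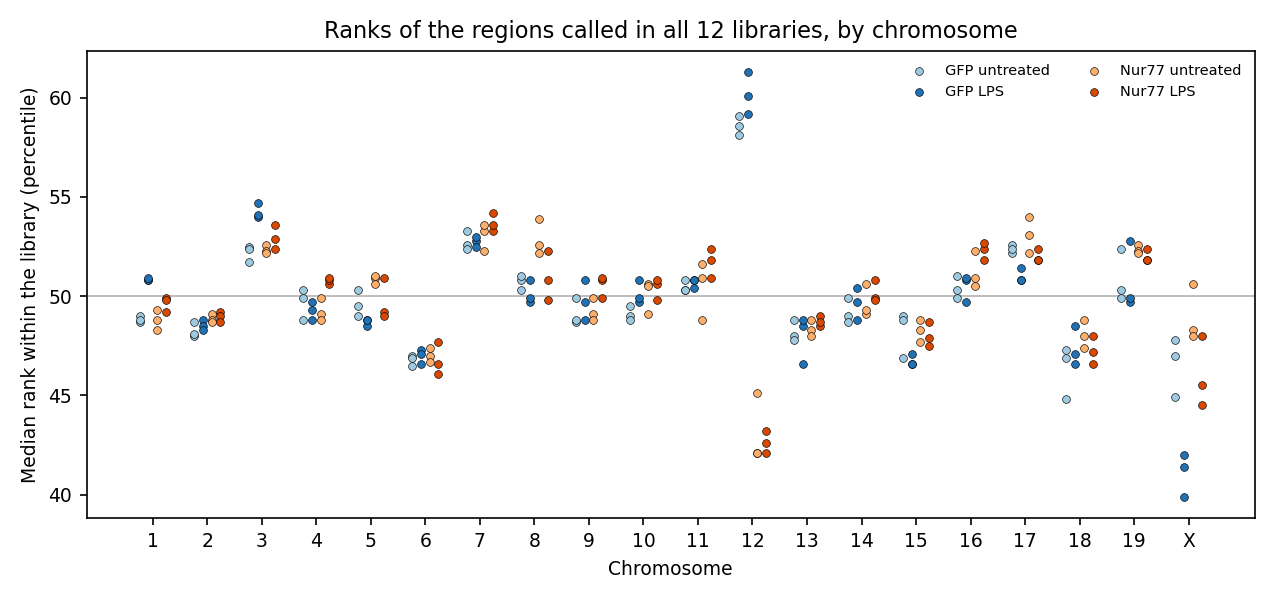
Median within-library percentile of the regions called in all 12 libraries (vertical axis) for each chromosome (horizontal axis), with 1 point per library coloured by group. On chromosome 12 the Nur77 libraries lie between 42.1 and 45.1 and the GFP libraries between 58.1 and 61.3.

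A further question was whether the response to LPS differed between the lines. Of the 1487 regions gained with LPS in the GFP line, 568 (38.2%) were called in 3 of 3 LPS-treated Nur77 libraries and 417 (28.0%) in none, among them regions near Ccl2, Rsad2, Il10, Ier5 and Batf3. Of the 1475 regions gained in the Nur77 line, 905 (61.4%) were called in 3 of 3 LPS-treated GFP libraries and 41 (2.8%) in none. Grouped instead by calls in untreated GFP libraries, 204 (13.8%) of the same 1475 regions were already called in 3 of 3. These included regions at Zeb2 and Gbp5, a gene of interferon-inducible host defence. The 204 can overlap with the 905. These shares are from the lists as deposited and were not computed in lists of equal length. LPS-treated GFP lists held 62210 peaks on average and LPS-treated Nur77 lists 52514. Of the regions gained in the GFP line, those near inflammatory genes were called in 1.97 LPS-treated Nur77 libraries on average, against 1.64 for the rest (permutation test, two-sided p = 0.11). Regions gained in both lines numbered 432. Independent gains would give 161.0 among the 1477 regions called in exactly 3 of 6 libraries in each line (odds ratio 147.32, one-sided Fisher's exact test, p = 3.43e-242). Among these, 36 were gained in the GFP line only and 76 in the Nur77 line only. Regions gained in the Nur77 line both before and after LPS numbered 44. Independence would give 2.5 among 1499 regions chosen in the same way (odds ratio 229.03, one-sided Fisher's exact test, p = 1.14e-56). Most gained regions did not meet this rule and were left out of both tests. The odds ratios therefore overstate how far the full sets of gained regions overlap. Regions are not independent replicates in these tests.

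A region counted as a differing response when it separated the LPS libraries in one line and, in the other, changed by 0 libraries or in the opposite direction. There were 1266 such regions, comprising 474 gained and 358 lost in the GFP line and 322 gained and 112 lost in the Nur77 line, and 0 regions were gained in one line and lost in the other. Redrawing the line labels within treatments gave at least as many regions in 31 of 100 relabellings, and in lists of equal length in 7 of 100 (1438 regions). Such relabelling can turn a region that differs between the lines in both treatments into a differing response, which raises the relabelled counts. The test therefore cannot decide whether the response differed between the lines, and no difference was shown. The count of differing responses was 2901, 2059 and 3309 without GFP LPS replicates 1, 2 and 3, and 1945 without GFP untreated replicate 1. With 1 library left out, numbers of calls were compared between unequal numbers of libraries, so these counts are not comparable with 1266.

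At the level of whole lists, no measure passed the threshold. The LPS libraries held 2050 more peaks on average (p = 0.785, adjusted p = 0.9) and covered 0.92 Mb more (p = 0.9, adjusted p = 0.9), in exact permutation tests within lines. The Nur77 libraries differed from GFP by -11070 peaks (p = 0.115, adjusted p = 0.345) and -7.48 Mb (p = 0.32, adjusted p = 0.64), in exact permutation tests within treatments. The share of peaks within 1000 bp of a gene end ran from 14.66% to 26.85% over the libraries and differed by -1.0 percentage points with LPS (exact permutation test, p = 0.54, adjusted p = 0.81) and by 2.93 with Nur77 (exact permutation test, p = 0.105, adjusted p = 0.345). All were two-sided, with 400 relabellings and a smallest possible p of 0.005. In lists of equal length the differences in this share, -0.64 and 0.57 points, passed at p = 0.005 in exact permutation tests.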

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

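Peaks outside chromosomes 1 to 19, X and Y entered no comparison, and in the GFP line they numbered 59, 64 and 67 in the LPS libraries, above the highest value of 58 in the untreated libraries. In the Nur77 line they numbered 56, 52 and 71 with LPS and 62, 52 and 51 untreated. No explanation of this count was tested.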

How the results depend on the processing

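The choices at 10 and 20 times background, random gene lists and lists without chromosome 12 were tried only after the results had been seen. Of the values that answer a comparison, 477 kept their direction and their side of the threshold, or stayed within 1.5 times, over the alternatives tried. Another 75 moved further, 7 newly passed and 6 reversed, and except where stated the cause was not tested.

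With the strongest N peaks of each list, LPS in the Nur77 line gave 663 lost regions. Nur77 against GFP gave 690 gained and 1095 lost in untreated cells, and 763 and 1097 after LPS. Across 12 libraries, LPS regions past adjustment numbered 547 more and 95 less often called, with 95 called in none against all. Nur77 regions numbered 112 (all against none) and 269 (none against all), with 0 past adjustment. With the strongest 20000 peaks, LPS in the Nur77 line gave 903 gained regions, Nur77 gave 377 and 624 untreated and 458 and 732 after LPS, LPS gave 461 and 124 past adjustment (124 none against all), and Nur77 gave 66 and 186 past adjustment (186 none against all). With peaks at least 20 times background, LPS gave 465 lost regions in GFP cells, Nur77 gave 448 gained and 1061 lost untreated and 580 gained after LPS, LPS gave 726 (all against none) with 726 and 51 past adjustment, and Nur77 gave 103 (all against none) and 281 (none against all) with 0 past adjustment. At 10 times, Nur77 against GFP gave 469 regions gained after LPS. Windows of 100 bp either side of summits gave 1175 regions lost with LPS in GFP cells and 62 called in none against all. A call that needs peaks over at least 50% of the region gave 363 regions gained with Nur77 untreated and 62 called in none against all with LPS. The planned wording of that overlap rule was always met, so this form was run.

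Gene-end shares passed at -0.64 (LPS) and 0.57 (Nur77) points in the strongest N peaks, -1.82 and 1.29 in the strongest 20000, and -4.18 (LPS) in the strongest 10000. The count of tests past the threshold was 0 for cytokines and chemokines within 10 kb, at 20 times background and with random lists, and within 100 kb the test that passed was in the GFP line instead of the Nur77 line. It was 2 for the NF-kB list within 10 kb (odds ratios 15.26 in the GFP and 22.97 in the Nur77 line), 1 within 100 kb and 0 in the strongest N, at 20 times and with random lists. It was 1 for lipid and energy metabolism within 10 kb and 0 within 100 kb, in the strongest N, at 20 times and with random lists.

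Leaving out 1 library loosens the criterion to 2 of 2, which by itself raises counts. Ranges were 1550 to 3962 gained and 837 to 3650 lost with LPS in GFP cells, 1520 to 2807 and 413 to 2032 in Nur77 cells, 294 to 1193 and 2679 to 5227 for Nur77 untreated, and 251 to 1382 and 1761 to 5110 for Nur77 after LPS. Across 12 libraries they were 434 to 613 and 39 to 130 for LPS and 44 to 77 and 433 to 767 for Nur77, and 1006 to 3309 for differing responses. The last range compares calls between unequal numbers of libraries and is not comparable with the count from all 12. Differences with LPS ran from -2765 to 5533 peaks, -4.41 to 5.05 Mb and -1.75 to 0.18 points of gene-end share. They turned without Nur77 untreated replicate 2 (all 3), without GFP LPS replicate 3 (-2765 peaks, -4.41 Mb) and without Nur77 LPS replicate 1 (-1.39 Mb). With Nur77 they ran from -14549 to -6251 peaks, -11.6 to -2.15 Mb and 1.75 to 3.68 points, and peaks and points newly passed without GFP LPS replicate 1.

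Replicate numbers recur across groups, but libraries with equal numbers did not deviate together (correlations -0.027 to 0.059), so pairing was not used. With a replicate block the 12-library tests called 0 regions, which was fixed in advance and is no check. The smallest p of this form is 0.03125, which only regions called in exactly 6 libraries can reach. These number 4157, too few among 20292 tested for any to pass adjustment. With the block the peak number differed by 2050 with LPS (exact sign flips, two-sided p = 0.656) and -11065 with Nur77 (p = 0.219, smallest possible 0.03125). Of the named regions, 175 separated the groups in the strongest N peaks and 139 no longer did, against 161 and 153 at 20 times background and 83 and 231 in the strongest 20000, and 0 reversed. Motif alternatives were not run. Depth limits the calls: peaks below 5 to 8 reads were not listed.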

Other observations

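The tests on chromosome 12, on depth and list length and on splits of 3 against 3 libraries were chosen only after the results had been seen, as was the threshold of 20 times background that the count over chromosomes uses. The other tests here were planned before.

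Several gene groups held single regions that separated the lines. The ranks given lay below the middle of the lists, where depth bears on whether a region is called. After LPS, the Nur77 line had a gained region inside Il4ra, the gene of an interleukin 4 receptor chain (percentile 45.7 ± 6.7, n = 3), one inside Irf1, an interferon regulatory factor gene (14.8 ± 5.4, n = 3), and one 21.0 kb from Ifnb1, the interferon beta gene (24.2 ± 0.4, n = 3). A region inside Nr1h3, which encodes the liver X receptor alpha, was called in 3 of 3 libraries of each other group and in 0 of 3 LPS-treated Nur77 libraries (27.3 ± 22.5 in LPS-treated GFP cells, n = 3). In untreated cells, lost regions near anti-inflammatory genes lay near Il10, near Tsc22d3 and at 3 sites near Il1rn, the gene of the interleukin 1 receptor antagonist.

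None of these lists passed Fisher's exact test over the 4 comparisons. The lowest adjusted p was 0.51 for interferon response and for nuclear receptors, 0.7 for the AP-1 family and for the other immediate early genes, 0.84 for housekeeping and 1.0 for macrophage identity and for anti-inflammatory genes, all by two-sided Fisher's exact test. Markers of other cell types gave 0.25 (epithelium), 0.45 (T cells), 0.7 (fibroblasts) and 1.0 (B cells and neurons) in the same exact tests. At an unadjusted p under 0.05 stood 1 test each for interferon response, nuclear receptors, T cells and epithelium.

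In the Nur77 line more regions were lost than gained against GFP, 91.7% and 87.8% of the separating regions in untreated and LPS-treated cells. Loss of chromosome copies as the whole cause is argued against, since 19 of 20 chromosomes had more lost than gained regions in both treatments at 20 times background. Lower depth of the Nur77 libraries stays open: the lost share was 70.3% and 67.6% at that height and 61.3% and 59.0% in lists of equal length, where it stayed at 52.0% to 62.7% with each library left out. At 20 times background without Nur77 LPS replicate 2 it was 50% (1339 lost and 1339 gained), at the bound where depth could account for the direction. An effect of Nur77 itself, or a difference between the lines that preceded induction, also stays open, because each protein was carried by 1 line.

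Regions lost in the Nur77 line lay more often on chromosome 12. A candidate explanation is a different number of copies of chromosome 12 in the lines: in 11 of 11 windows of 10 Mb with at least 20 regions the mean rank was lower in the Nur77 libraries, as copies of the whole chromosome would need. A change in one stretch is argued against by the smallest difference in these windows, -9.5, and the window left out (40 to 50 Mb, 15 regions) differed by -7.2, with the libraries of the lines overlapping. Lower depth is argued against by the other chromosomes, whose largest difference was 3.7 against -16.5. This remains a hypothesis, since copy number was not measured, and without chromosome 12 the regions called in all against none and in none against all for Nur77 were 44 and 366.

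With LPS more regions were gained than lost in both lines. Deeper LPS libraries are argued against, since the gained share at 20 times background did not go below 68.1% in either line or with any library left out, and the mean background height was lower with LPS (0.846 against 1.008 reads in the GFP line, 0.755 against 0.805 in the Nur77 line). At 20 times background the LPS lists were longer (36099 against 32955 and 35071 against 31425 peaks on average), which by itself favours gains there. Longer lists in the LPS libraries are argued against in the same way by lists of equal length, where the lowest share was 56.8%. A response to LPS stays open as the biological explanation and may hold for the regions gained in both lines.

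A planned test asked whether regions gained with LPS lie away from gene ends, and the higher of the odds ratios of the lines was 0.67, below 1 in both. Another asked whether, among regions gained with LPS in the GFP line, those near inflammatory genes were called in fewer LPS-treated Nur77 libraries than the rest. They were called in 1.97 libraries on average (38 regions) against 1.64 (1449 regions), a difference of 0.33 (permutation test, two-sided p = 0.11), so the data do not show the lower calling that was asked about and do not decide the question.

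Other splits of the libraries were counted beside each result. For 3 against 3, the 10 splits are too few for a share under 0.05. The real split gave 2264 separating regions for LPS in the GFP line (highest other 2176, 1 of 10 splits as large), 1825 for LPS in the Nur77 line (highest other 1913, 2 of 10), 2822 for Nur77 in untreated cells (highest other 948, 1 of 10) and 1892 for Nur77 after LPS (highest other 1712, 1 of 10). In each case the highest other split parted the 3 libraries of highest background height from the 3 of lowest, and in lists of equal length it gave 10.9%, 24.9%, 16.2% and 12.7% of the real count. Across 12 libraries, only the real split by LPS, 1 of 100, reached its count of regions called in all against none or none against all (470, highest other 77). The same held for the split by line (476, highest other 141, 1 of 100). Random grouping of single libraries therefore does not account for these counts. Random splits break up the groups of 3, so a culture or batch shared within a group is not excluded. For differing responses to LPS, 31 of 100 relabellings gave at least 1266 regions (highest other 3380). In lists of equal length 7 of 100 gave at least 1438 (highest other 1746). The relabelled counts also take in regions that differ between the lines in both treatments. Chance is therefore not excluded in either, and these shares cannot decide the question.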
